A study of Mus musculus with 8 samples.

How the data were processed

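RNA was measured in endothelial cells sorted by flow cytometry from the lungs of C57BL/6J mice that had received an adeno-associated virus (AAV), a vector used to deliver a gene to tissue. Per the labels, 4 libraries came from mice given a control AAV and 4 from mice given an nANGPTL4 AAV, and the 4 of each group were independent biological replicates. The titles and count columns of the nANGPTL4 AAV group read NT Treated, an abbreviation that the labels do not explain, so the identity of that group rests on the treatment field, while the other group is named as control in both. Per the labels' protocols, RNA was isolated with a kit for very small samples, and cDNA made with a low-input kit was turned into libraries with a ChIP-seq library kit. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, its strand setting and the gene annotation were not given in the sources used here.

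The deposited values were whole-number read counts per gene, not normalized, for 31610 Ensembl genes in 8 libraries, and 47 genes had no count in any library. Of the gene identifiers, 31491 were matched to a symbol without their version number and 26730 with it. Coordinates, exons, transcript length and GC content came from the GENCODE M21 annotation, which uses the same genome build. Total counts ranged from 83183122 to 114337333 per library, and 26652 to 29969 genes had at least 1 count. No per-sample column was left unmapped.

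The comparison between the groups used edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by filterByExpr with its minimum count of 10, library sizes were scaled by TMM, and the quasi-likelihood F test was applied with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the 18874 genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are nANGPTL4 AAV minus control AAV, with a standard error (SE) from the same fit. CPM values, which divide a count by the scaled library size, were computed from the deposited counts with TMM scaling, and log2 CPM used a prior count of 2. The mean and SD of CPM are over the 4 libraries of a group throughout. The biological coefficient of variation was 11.3%, and the median SE of a log2 fold change among genes with a mean log2 CPM over 3 was 0.06.

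Gene lists for cell types and pathways were fixed before the data were examined. The 38 lists with at least 3 measured members were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with a correlation estimated from the residuals, and the rotation test fry, were run as alternatives. Single values per library were compared by an exact two-sided permutation test over the 70 arrangements of 8 libraries into 2 groups of 4, whose smallest possible p is 0.0286.

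The genes named in the text follow a rule fixed before the data were examined. Angptl4, Lpl, Gpihbp1, Cd36 and Fabp4 were named whatever their result. Up to 12 called genes in each direction with the largest absolute log2 fold change were named if their mean log2 CPM was at least 1 and the groups did not overlap, and genes with a provisional symbol were skipped. This gave 6 genes higher, 1 of them skipped for its symbol, and the first 12 of 17 genes lower. Up to 4 members with the smallest p were named for a list that was called or held a called gene, and up to 2 for any other list. Some genes that the rule names are not reported here. Genes named outside the rule for their change or level are said to have been chosen after their values were seen. Others serve as endothelial markers, as overlapping genes, as shared list members or as clock genes in a test.

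The fits were tested on simulated counts for the same 18874 genes, with the real means and library sizes and 200 genes changed by known folds. The changed genes were drawn from those with a mean log2 CPM over 1. Of the 50 genes changed at each fold, 48% were recovered at a fold of 1.25, 96% at 1.5, 100% at 2 and 100% at 4, with 19 unchanged genes called. With no gene changed, 0 genes and 0 lists were called, in counts simulated without correlation between genes. With the real libraries, splits other than the real one called a median of 7 lists. When a GC trend between the groups was added, 518 unchanged genes were called before and 7 after the GC and length correction.

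The alternatives tried were other scalings, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom with quality weights, a robust edgeR fit, the replicate number as a block, each library left out in turn, and other thresholds. A score of other cell types, the mean log2 CPM of the 57 measured members of the lymphocyte, myeloid, epithelial, fibroblast and mural, and erythroid and platelet lists, as a covariate, a correction for GC content and transcript length, and the removal of 2 libraries together were added after the data were seen. Transcript sequences of the named and called genes were compared with those of all other annotated genes by shared stretches of 31 bases, and their exons with exons of other genes on either strand.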

Results

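ANGPTL4 is a secreted inhibitor of lipoprotein lipase, the enzyme that releases fatty acids from circulating triglycerides at the capillary wall, and nANGPTL4 is its N-terminal fragment. The series set sorted lung endothelial cells of mice given an nANGPTL4 AAV against those of mice given a control AAV, which asks how endothelial gene expression differs when the fragment is delivered. Read counts per gene were available for 4 libraries in each group. Total counts were 94056725, 114337333, 83183122 and 100607473 in control AAV libraries 1 to 4, and 91750817, 98974566, 108921765 and 100693992 in nANGPTL4 AAV libraries 1 to 4. Log2 CPM correlated across genes with r between 0.991 and 0.994 over all pairs of libraries. Replicates of one group differed by more than counting error alone in every pair, with a chi-square of 20.97 to 60.81 per degree of freedom. That measure allows for no difference between mice or in library preparation. Endothelial transcripts were abundant in both groups, with Pecam1 at a mean of 2734 CPM in control AAV and 2647 CPM in nANGPTL4 AAV and Cdh5 at 1194 and 1153 CPM.

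The clearest difference was in Agpat2, which encodes an acyltransferase that makes phosphatidic acid on the way to triglycerides and phospholipids. Agpat2 rose from 33.1 ± 2.19 CPM in control AAV to 55.9 ± 3.88 CPM in nANGPTL4 AAV (SD, n = 4 each), a log2 fold change of 0.76 (SE 0.06, adjusted p = 0.00254, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Gja5, which encodes a gap junction protein of arterial endothelium, fell from 96.9 ± 8.31 to 64.0 ± 4.30 CPM, a log2 fold change of -0.60 (SE 0.07, adjusted p = 0.0317 by the same test). Fli1, an ETS transcription factor of endothelial and blood cells, fell from 172 ± 14.9 to 119 ± 8.28 CPM, a log2 fold change of -0.53 (SE 0.07, adjusted p = 0.0369 by the same test). In all, 26 of 18874 genes were called, 9 higher and 17 lower in nANGPTL4 AAV, with absolute log2 fold changes from 0.26 to 1.58 and a median of 0.45.

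The other named genes that rose were Slc16a11, a member of the monocarboxylate transporter family, by a log2 fold change of 0.62, Acvr2b, an activin receptor, by 0.36, Zswim4 by 0.32, and Nbl1, a secreted antagonist of bone morphogenetic proteins, by 0.28. Their adjusted p-values in the edgeR test lay between 0.0369 and 0.0493. Of the other named genes that fell, the log2 fold change was -0.66 for Banp, -0.53 for the LIM homeobox factor Lhx6, -0.45 for Kansl1l and -0.30 for the heterochromatin factor Bahd1. It was -0.56 for the tubulin-modifying enzyme Ttll4, -0.52 for the phosphoinositide phosphatase Mtmr4, -0.46 for Neto2, -0.38 for the signal peptidase subunit Spcs3, -0.37 for the ribosome biogenesis factor Heatr1 and -0.36 for Osmr, the oncostatin M receptor. Hif1a, the oxygen-regulated transcription factor, lay just outside the naming rule and was chosen after its values were seen, with a log2 fold change of -0.30 (SE 0.04, adjusted p = 0.0369). In each of the 26 called genes every nANGPTL4 AAV library lay on one side of every control AAV library, as did 10.9% of all tested genes, where chance gives 2.86%. The 3 called genes with an absolute log2 fold change of at least 1 were Mst1r, Scgb3a2 and Epn3, chosen here after their values were seen. Each had a mean log2 CPM under 1, and Scgb3a2 is a secretory gene of airway epithelium, at 0.328 ± 0.0513 CPM in control AAV and 0.804 ± 0.106 CPM in nANGPTL4 AAV.

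Agpat2 lies on chromosome 2 at 26593057 to 26604417 on the minus strand of mm10, Gja5 on chromosome 3 at 96904693 to 97077416 on the plus strand, and Angptl4 on chromosome 17 at 33773750 to 33781830 on the minus strand. The counts are totals over annotated genes, so no exon or isoform can be singled out. Of the exonic bases of Agpat2, 3.0% overlap Egfl7 on the other strand, which is far more abundant at 2444 and 2316 CPM and had a log2 fold change of -0.08. Of those of Kansl1l, 16.7% overlap an unnamed gene on the other strand and 8.37% overlap Rpe, 5.60% of those of Hif1a overlap an antisense gene, and 14.2% of the 31-base stretches of Gja5 recur in other genes. The counts of these genes, Agpat2 included, are less certain. An unadjusted p under 0.05 was found for 3331 genes, 1388 higher and 1943 lower, where 944 are expected on average with no difference. Among the other splits of the 8 libraries into 4 and 4 the highest count was 1997. A split with 2 control libraries on each side reached 1718, so counts well above 944 arise without the group difference. The size of the called set depended on the libraries and the tool: leaving out any 1 of the 8 libraries left 1 or 2 genes, DESeq2 called 308 higher and 648 lower, and upper quartile scaling or library size alone called 3 higher and 1 lower. Agpat2 was called in each of 20 alternative fits and Gja5 in 10 of them.

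**Figure D1:**
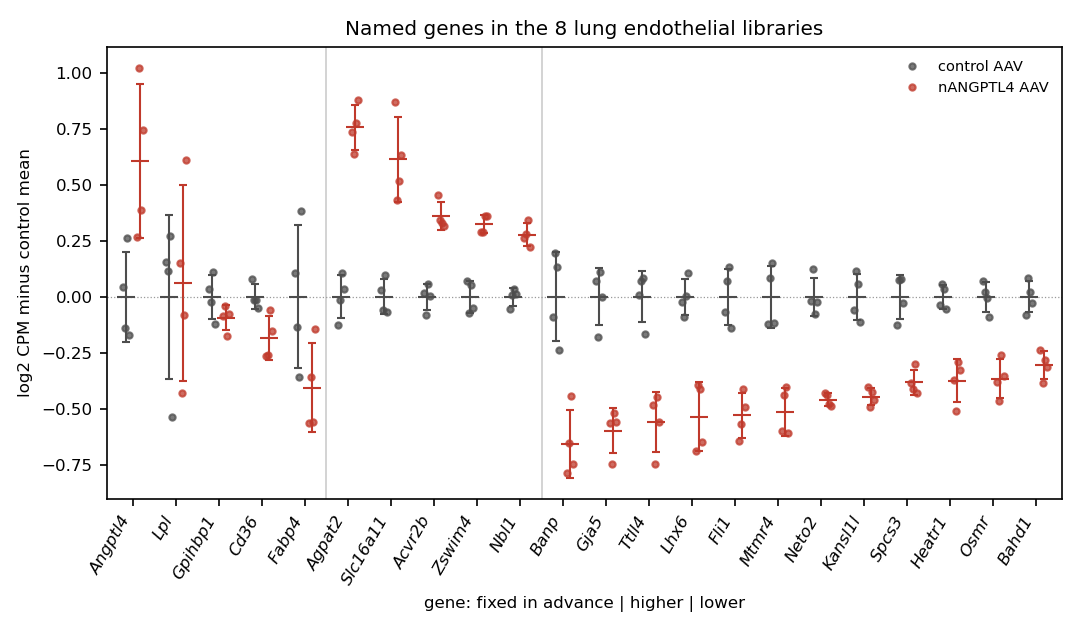
Log2 CPM of the named genes, each minus its control AAV mean (vertical axis), for the 5 genes fixed in advance, the 5 named higher and the 12 named lower (horizontal axis). Points are single libraries and bars are the mean ± SD of 4 libraries per group; the groups do not overlap for any of the 17 called genes, while Lpl spans both groups.

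Angptl4 itself, the mouse gene of the delivered protein, had 304, 332, 321 and 285 counts in control AAV libraries 1 to 4 and 360, 667, 465 and 558 counts in nANGPTL4 AAV libraries 1 to 4. This is 3.26 ± 0.466 and 5.04 ± 1.23 CPM (SD, n = 4 each), a log2 fold change of 0.63 (SE 0.17) that did not pass the threshold over all genes in the edgeR test (adjusted p = 0.110). Every nANGPTL4 AAV library was above every control AAV library, but nANGPTL4 AAV library 1 (3.893 CPM) and control AAV library 3 (3.883 CPM) were nearly tied. DESeq2 gave an adjusted p of 0.00901. Whether reads from the vector could be counted under this gene is not stated. Lpl, which encodes lipoprotein lipase, was at 190 ± 42.6 and 201 ± 62.1 CPM, a log2 fold change of 0.08 (SE 0.21, edgeR adjusted p = 0.877) that was -0.07 without control AAV library 4 and -0.13 without nANGPTL4 AAV library 4. Gpihbp1, the capillary anchor of lipoprotein lipase, was at 760 ± 50.8 and 711 ± 27.0 CPM (log2 fold change -0.10, SE 0.06, edgeR adjusted p = 0.405).

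Of the lipid lists, fatty acid and triglyceride synthesis held the only called member, Agpat2, out of 15 measured, and 3 members passed when adjusted over the list alone. These were Agpat2, the phosphatidic acid phosphatase Lpin1 with a log2 fold change of 0.41, and the elongase Elovl5 with -0.13. The median of that list was 0.01 and its camera adjusted p was 0.609. With library size only in place of TMM scaling the median was 0.05. In the fatty acid uptake list, 18 of 23 members had negative values, with a median log2 fold change of -0.05 and a camera adjusted p of 0.0754. With library size only this median was -0.01. All genes with a mean log2 CPM over 3 had a median of -0.03 with TMM scaling, so the median of this list lay near that of expressed genes. None of its members was called over all genes, and 2 passed when adjusted over the list alone, the transporter Slc27a4 at -0.22 and the caveolar protein Cav1 at -0.18. Cd36, a fatty acid transporter, had a log2 fold change of -0.18 (SE 0.06, adjusted p = 0.145) and the fatty acid binding protein Fabp4 one of -0.42 (SE 0.15, adjusted p = 0.181). The 13 measured members of the list for ANGPTL4 and lipoprotein lipase went both ways, and its median (-0.01), mean (0.05) and test direction (lower) differed in sign, the median being 0.04 with library size only, with a camera adjusted p of 0.904. Angptl4 was the only one of them that passed when adjusted over the list alone, and 0 passed over all genes. In the list of PPAR targets and fatty acid oxidation the camera adjusted p was 0.510, and Pparg, which passed when adjusted over the list alone and not over all genes, had a log2 fold change of -0.91 at 1.48 and 0.792 CPM.

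Of the 38 gene lists, 11 passed the camera test with the preset correlation, 7 lower and 4 higher in nANGPTL4 AAV. None of the 11 passed when the correlation was estimated, and 8 of the 35 ways to split the libraries into 4 and 4, the real one included, called 11 or more lists. The lower lists included markers of vessel types other than the gas-exchange capillary. All 11 venous markers had negative values, with a median log2 fold change of -0.24 (camera adjusted p = 0.000804, and adjusted p = 0.373 with an estimated correlation). No venous marker passed over all genes and 6 passed when adjusted over the list alone, among them the Eph receptor Ephb4 at -0.24, the coagulation protein Vwf at -0.27, Cpe at -0.27 and Prss23 at -0.29. Prss23 shares 22.9% of its exonic bases with an antisense gene, so its counts are less certain. Of 14 arterial markers 11 had negative values, with a median of -0.21 (camera adjusted p = 0.0214, and adjusted p = 0.320 with an estimated correlation). This list no longer passed without nANGPTL4 AAV library 4 (camera adjusted p = 0.0540) or with the stricter low-count filter (camera adjusted p = 0.0767). Gja5 was the only one called over all genes, and 4 passed when adjusted over the list alone, Gja5, Vegfc at -0.37, Efnb2 at -0.21 and, in the other direction, Stmn2 at 0.14. General capillary markers had a median of -0.10, with 9 of 10 negative (camera adjusted p = 0.00672, and adjusted p = 0.333 with an estimated correlation). With upper quartile scaling and with library size only that median was -0.06. None passed over all genes and 3 passed when adjusted over the list alone, Cd93 at -0.29, Sema3c at -0.23 and Ptprb at -0.18. Markers of aerocytes, the gas-exchange capillary cells, had a median of 0.07 (0.11 with library size only) with 10 of 12 positive (camera adjusted p = 0.373), and Kitl at -0.13 and Igfbp7 at 0.12 had the smallest p. Pan-endothelial markers had a median of -0.05 with 14 of 16 negative (camera adjusted p = 0.0749) and Flt1 at -0.15 and Tek at -0.13 as the members with the smallest p. The pan-endothelial median was -0.01 with upper quartile scaling and -0.0026 with library size only. With TMM scaling it lay near the median of all genes with a mean log2 CPM over 3, which was -0.03. Lymphatic markers had a median of -0.16 (camera adjusted p = 0.162). That an aerocyte list did not pass while others did is not a test of the difference between them.

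Notch pathway genes, which share Efnb2, Hey1 and Dll4 with the arterial list, had a median log2 fold change of -0.20, with 13 of 15 negative (camera adjusted p = 0.00561, and adjusted p = 0.320 with an estimated correlation). None passed over all genes and 3 passed when adjusted over the list alone, the receptor Notch1 at -0.27, the ligand Jag1 at -0.42 and Efnb2 at -0.21, while the ligand Dll1 was at -0.48 without passing. An antisense gene overlaps 20.6% of the exonic bases of Dll1, and 2 antisense genes overlap 7.50% and 2.91% of those of Notch1. Basement membrane and integrin genes had a median of -0.08 (camera adjusted p = 0.00672, and adjusted p = 0.373 with an estimated correlation). With upper quartile scaling and with library size only that median was -0.04. The list no longer passed without control AAV library 2 (camera adjusted p = 0.0538) or with the stricter low-count filter (camera adjusted p = 0.0574). None of the 24 passed over all genes and 4 passed when adjusted over the list alone, all of them integrin alpha subunits, with Itga5 at -0.36, Itga6 at -0.27, Itga2 at -0.21 and Itga1 at -0.16. Glycocalyx genes had a median of -0.08 (camera adjusted p = 0.0133, and adjusted p = 0.320 with an estimated correlation). Their median too was -0.04 under these scalings, and with the stricter low-count filter the list did not pass (camera adjusted p = 0.0832). Of 21 members 0 passed over all genes and 2 when adjusted over the list alone, the heparan sulfate enzyme Ndst1 at -0.22 and the hyaluronan synthase Has2 at -0.92. Has2 had very few counts, with a mean of 0.309 CPM in control AAV and 0.163 CPM in nANGPTL4 AAV. Genes of the unfolded protein and integrated stress response had a median of -0.14 with 15 of 19 negative (camera adjusted p = 0.00672, and adjusted p = 0.410 with an estimated correlation). This list no longer passed without control AAV library 2 (camera adjusted p = 0.0695). None passed over all genes and only the secreted stress protein Manf, at -0.27, passed when adjusted over the list alone, while the transcription factor Xbp1 was at -0.33. The rotation test fry, which asks only whether a list's genes move one way on balance, passed 5 lists at an adjusted p under 0.05, those for general capillary, arterial, junction, glycocalyx and Notch genes. Junction and barrier genes had a median of -0.06, which was -0.01 with library size only (camera adjusted p = 0.0611). The median of all genes with a mean log2 CPM over 3 was -0.03 with TMM scaling. Of the 20 junction genes 0 were called over all genes, and Jam2 at -0.29 was the only one to pass when adjusted over the list alone.

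**Figure D2:**
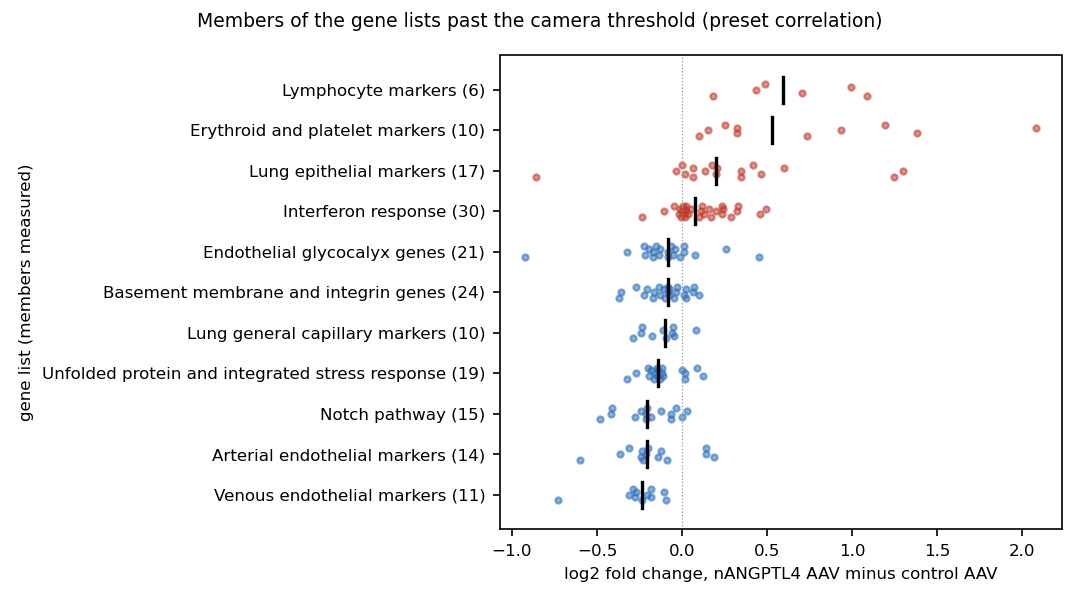
Log2 fold change (nANGPTL4 AAV minus control AAV, horizontal axis) of each measured member of the 11 lists past the camera threshold with a preset correlation (vertical axis, number of members in brackets). Points are genes and black lines list medians, from -0.24 for venous markers to 0.60 for lymphocyte markers; none of these lists passed with an estimated correlation.

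Interferon response genes were higher as a list, with 23 of 30 positive and a median log2 fold change of 0.08, which was 0.12 with library size only (camera adjusted p = 0.00955, and adjusted p = 0.610 with an estimated correlation). The list no longer passed without control AAV library 2 (camera adjusted p = 0.0524). None passed over all genes and 4 passed when adjusted over the list alone, Isg15 at 0.33, Rsad2 at 0.46, Usp18 at 0.23 and Ifit3 at 0.32. Of the sequence of Ifit3, 61.8% recurs in its copy Ifit3b, and 12.8% of that of Isg15 recurs in other genes, so both counts are less certain.

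Of the lists for other cell types, 3 passed with the preset correlation. Erythroid and platelet markers, all 10 of them positive, had a median of 0.53 (camera adjusted p = 0.00561, and adjusted p = 0.373 with an estimated correlation). Lymphocyte markers, with 6 of 14 listed genes measured and all 6 positive, had one of 0.60 (camera adjusted p = 0.0214, and adjusted p = 0.410 with an estimated correlation). Lung epithelial markers had a median of 0.20 with 15 of 17 positive (camera adjusted p = 0.0343, and adjusted p = 0.688 with an estimated correlation). The epithelial list passed in 9 of 19 alternative settings. It did not pass with upper quartile scaling (camera adjusted p = 0.115) or library size only (camera adjusted p = 0.117). Nor did it without control AAV library 1 (camera adjusted p = 0.909) or nANGPTL4 AAV library 1 (camera adjusted p = 0.0741), 2 (0.0860) or 4 (0.0834). The lymphocyte list did not pass with library size only (camera adjusted p = 0.0513) or without control AAV library 2 (camera adjusted p = 0.0524) or nANGPTL4 AAV library 2 (0.0913). The erythroid and platelet list did not pass with the stricter low-count filter (camera adjusted p = 0.0832). Scgb3a2 was the only epithelial marker called over all genes, and 3 passed when adjusted over the list alone, Scgb3a2, the club cell gene Scgb1a1 and, lower, the ciliated cell gene Foxj1. Scgb1a1 was at 13.4 ± 7.74 and 31.7 ± 7.06 CPM, Foxj1 at 1.86 ± 0.770 and 1.03 ± 0.141 CPM, and Cldn18 at 12.6 ± 4.77 and 19.0 ± 1.47 CPM (SD, n = 4 each). No erythroid or platelet marker passed over all genes and 2 passed when adjusted over the list alone, the globin genes Hbb-bt at 2.08 and Hba-a2 at 1.38, whose sequences are shared with other globin genes. Both had very few counts, with means in control AAV and nANGPTL4 AAV of 0.0494 and 0.204 CPM for Hbb-bt and 0.178 and 0.459 CPM for Hba-a2. No lymphocyte marker passed either way, and Cd79b and Lck had the smallest p. Hopx, Sftpc, Ppbp and Hbb-bs were chosen after their values were seen. The alveolar epithelial genes Hopx and Sftpc had means of 252 and 88.5 CPM in control AAV and of 276 and 112 CPM in nANGPTL4 AAV. The platelet gene Ppbp had means of 19.9 and 22.1 CPM in control AAV and nANGPTL4 AAV. The haemoglobin gene Hbb-bs was at 1.67 ± 0.808 and 3.78 ± 2.25 CPM (SD, n = 4 each), with overlap between the groups. Myeloid markers had a median of 0.35 (camera adjusted p = 0.0620) with Cd68, at 0.46, passing when adjusted over the list alone and not over all genes, and fibroblast and mural cell markers had a median of 0.20 and a mean of 0.04 (camera adjusted p = 0.692). Of the members of these marker lists, 0 of the lymphocyte, epithelial, erythroid and platelet genes stood in another list.

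Per library, the mean log2 CPM of erythroid and platelet markers was 0.97 ± 0.39 in control AAV and 1.68 ± 0.32 in nANGPTL4 AAV, which did not separate the groups fully (exact two-sided permutation p = 0.0571, adjusted over 13 measures 0.223). Lymphocyte markers were at -0.96 ± 0.14 and -0.41 ± 0.49 (exact permutation p = 0.0571), epithelial markers at 2.45 ± 0.57 and 2.81 ± 0.20 (exact permutation p = 0.314), and pan-endothelial markers at 10.18 ± 0.03 and 10.13 ± 0.03 (exact permutation p = 0.0857). Control AAV library 1 had the lowest epithelial value, 1.61, and nANGPTL4 AAV library 2 the highest lymphocyte value, 0.28. Without both libraries the epithelial list turned lower with a camera adjusted p of 0.796, and the lymphocyte and erythroid lists no longer passed, with camera adjusted p-values of 0.0980 and 0.0657. The TMM factor, 0.985 ± 0.0111 in control AAV and 1.02 ± 0.00823 in nANGPTL4 AAV, was the only one of the 13 measures that separated the groups (exact permutation p = 0.0286, the smallest possible, adjusted 0.223).

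**Figure D3:**
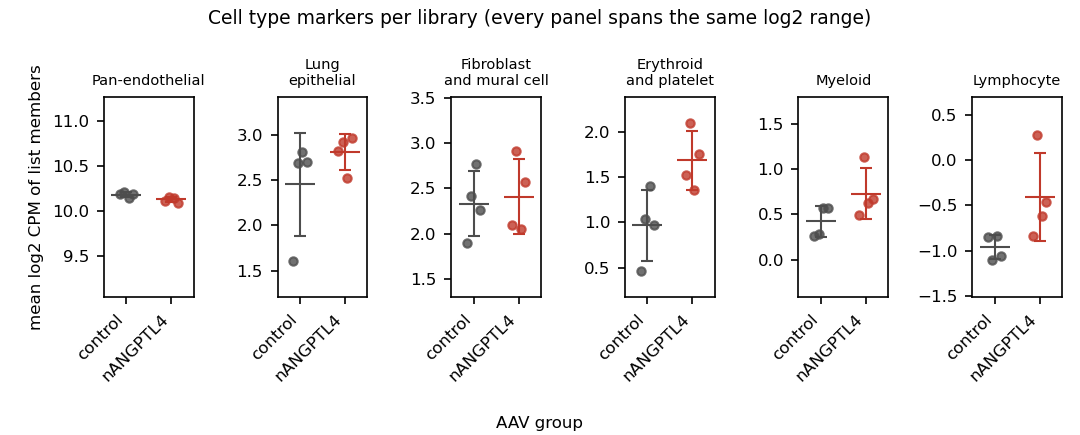
Mean log2 CPM of the members of 6 cell type marker lists (vertical axes, all spanning the same log2 range) in each library of the control AAV and nANGPTL4 AAV groups (horizontal axes). Points are libraries and bars the mean ± SD of 4; pan-endothelial markers lie near 10.18 and 10.13, while erythroid and platelet markers lie at 0.97 and 1.68.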

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

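The tests of chance for the called genes, of dilution for the lower lists and of the other cell types against each other were chosen after their results were seen, as were the covariate, the GC and length correction and the removal of libraries.

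In 8 of 256 groups of 4 values examined, 1 library stood far from the other 3, where chance flags about 1 in 20 groups, or 12.8. The figures that follow are the gap to the nearest library as a share of the group's whole range. Among the nANGPTL4 AAV libraries these were Clock (0.956, library 4 high), Ddit3 (0.955, library 4 low), Cd68 (0.923, library 2 low), Tek (0.913, library 3 low), Jam2 (0.834, library 4 high) and the percentage of counts in the top 10 genes (0.908, library 1 high). Among the control AAV libraries they were Aplnr (0.883, library 3 low) and the mean of the epithelial markers (0.897, library 1 low).

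The first pattern is the set of 26 genes called between the groups. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, called as many genes, and the highest of the others called 14. The real split thus called the most, but 1 of 35 is the smallest share this test can give. It was also chosen after its result was seen, so chance is not excluded. With each library's GC content and length trend taken out, the median called gene had 95.4% of its log2 fold change (lower quartile 88.1%). This argues against that trend as the whole of the pattern. With the other-cell score as a covariate the median called gene had 99.7% (lower quartile 94.5%), so the score did not account for the pattern. The genes were called in these same data, and the score is not shown to track dilution, as set out for the second pattern. The covariate therefore cannot exclude RNA of other cell types. Yet of these genes, whose adjusted p-values reached 0.0493 to begin with, only Agpat2 passed in each of these fits. Under the GC and length correction the median absolute log2 fold change of the 26 genes went from 0.45 to 0.39, the median SE stayed at 0.06, and their adjusted p-values rose to at most 0.0663; with the covariate the median was 0.46, the median SE rose from 0.06 to 0.07 and the adjusted p-values reached 0.200. A response of the endothelium to nANGPTL4 may underlie these differences, as a hypothesis found and tested on the same data. Chance, RNA of other cell types and differences between the mice other than the vector stay open.

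The second pattern is the 7 lists that were lower. For the count of lists chance could not be excluded, since 8 of the 35 splits called at least the 11 of the real split and the highest of the others called 14. Among the 110 distinct genes of the 7 lower lists, the pooled median log2 fold change (-0.09 with library size only) was -0.13 both before and after the GC and length correction, which kept 98.0% of it, so that trend is argued against. The other-cell score is the mean log2 CPM of 57 markers of other cell types, 0 of them in the 7 lists. With it as a covariate, all 7 lists still passed with the preset correlation and 112.5% of the pooled median was left. The difference in the members' mean per library was -0.16 (SE 0.04) against -0.14 (SE 0.03) without it, so the score did not account for the pattern. Dilution of endothelial RNA by other cell types would give that mean a negative slope on the score, and the slope was 0.07 (SE 0.06). The score is thus not shown to track dilution, and the covariate cannot exclude it. The mean of 109 members of the lower lists, minus that of the pan-endothelial markers, differed by -0.083 between the groups, with overlap (exact two-sided permutation p = 0.0571). Chance, dilution, and a shift in the mix of sorted vessel types, which was not tested, stay open.

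The third pattern is the higher level of erythroid and platelet markers. A lower share of endothelial cells would raise every other cell type alike. Over the lists for lymphocytes, myeloid cells, epithelium, fibroblasts and mural cells, and erythroid cells and platelets, the change in mean log2 CPM differed by at most 0.639, a range that the 70 arrangements of the libraries reached with an exact permutation p of 0.114. Of the 10 pairs of lists, 1 had a difference that separated the groups, erythroid and platelet against fibroblast and mural markers, the highest against the lowest. With 4 libraries per group, a uniform loss of purity and a rise of some cell types cannot be told apart. More blood in some of the sorted samples, from red cells (median log2 fold change 1.19 over 5 erythroid genes) more than platelets (0.25 over 5 genes), or a difference in the mice's blood, stays open. The haemoglobin gene Hbb-bs had a mean of 1.67 CPM in control AAV and 3.78 CPM in nANGPTL4 AAV, and the sort for endothelial cells was meant to remove such cells.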

How the results depend on the processing

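The alternatives were fixed before the data were examined, except that the covariate, the GC and length correction and the removal of 2 libraries were chosen after seeing the data. None of the 26 called genes changed sign in any alternative in which it was tested, and Agpat2 passed in all 20, with adjusted p-values from 4.69e-21 to 0.0356. The other calls moved with the setting, and unless stated the cause was not tested. Against 9 genes higher and 17 lower (34.6% higher), DESeq2 size factors gave 9 and 14, limma-voom 7 and 14, and no low-count filter 11 and 14. Upper quartile scaling and library size only each gave 3 and 1 (75% higher), and the stricter low-count filter 4 and 1, with 10076 genes tested. The DESeq2 Wald test gave 308 and 648, and the robust edgeR fit 16 and 43. An adjusted p below 0.1 gave 114 and 357, and requiring an absolute log2 fold change of at least 1 gave 3 and 0, by construction. The other-cell score as a covariate gave 1 and 0, the GC and length offset 1 and 0, and leaving out control library 1 and nANGPTL4 library 2 together 2 and 0, with 2469, 3319 and 2881 genes at an unadjusted p under 0.05. Leaving out 1 library at a time gave 1 to 2 genes higher and 0 to 1 lower, so each of the 8 libraries moved the counts, with fewer samples in each fit. No setting shifted the median of all genes by more than 0.0434 on the log2 scale. Same-numbered libraries did not deviate together, with correlations of 0.14, 0.17, -0.25 and -0.31, and not every library correlated best with its own number, so the numbers were not taken to pair the samples; with the number as a replicate block 1 gene was higher and 5 lower. The log2 fold change of Angptl4 ran from 0.49 to 0.75 with 1 library left out, and at 0.6353 it passed in the DESeq2 Wald test (adjusted p = 0.00901, against 0.0960 to 0.360 elsewhere; it was not tested under the stricter filter). The number of gene lists called by camera was 11, and 19 with no low-count filter, 0 with an estimated inter-gene correlation, 5 with fry in place of camera, and 8 to 17 with 1 library left out, the highest without control library 3. Without control library 2 the calls of the lymphocyte (adjusted p = 0.0524), interferon (0.0524), basement membrane (0.0538) and unfolded protein (0.0695) lists ended, and without nANGPTL4 library 4 that of the arterial list (0.0540). The lymphocyte call also ended without nANGPTL4 library 2 (0.0913), and the epithelial call without control library 1 (0.909) or nANGPTL4 library 1 (0.0741), 2 (0.0860) or 4 (0.0834). The log2 fold change of Lpl ranged from -0.1329 to 0.2379 with 1 library left out, being -0.0688 without control library 4. Under the GC and length offset the log2 fold change of Ndufa2 was -0.0043 and that of Rplp1 -0.0316. The camera direction of Lung epithelial markers reversed with the other-cell score as a covariate (adjusted p = 0.6704) and without the 2 libraries (0.7958). All 17 measured members of that list are among the 57 genes of the score, so the reversal under the covariate is in part built in. For single genes and lists, 2126 values kept their direction and side of the threshold, 284 lost it, 50 gained it and 6 reversed. Only called genes and lists could lose it, and the 2126 include values that never passed, so these totals do not measure the stability of calls. Apart from Agpat2 and Gja5, each called gene passed in 2 to 8 of the alternatives. At the real library sizes, 96% of simulated genes changed 1.5-fold were recovered and 48% of those with the smallest simulated change, so small changes can be missed. The simulation changed 200 genes with a mean log2 CPM over 1, while 26 genes were called in the real data, so recovery there may be lower. Other depths were not simulated.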

Other observations

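The tests of the PPAR targets and of the mean clock phase were chosen after the results were seen, and the covariate was an alternative added after the data were seen.

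Among 21 genes of vascular tone and coagulation, 0 passed over all genes and 3 passed when adjusted over the list alone, 1 higher and 2 lower. The median of the list was -0.07 (-0.03 with library size only in place of TMM scaling) and its camera adjusted p 0.143. In the TGF-beta and BMP list, 0 of 20 passed over all genes and 3 passed when adjusted over the list alone, 1 higher and 2 lower. The camera adjusted p of that list was 0.130. Angiogenesis genes had a median of -0.05 (-0.004 with library size only), with 16 of 20 negative and a camera adjusted p of 0.0754. The median of all genes with a mean log2 CPM over 3 was -0.03 with TMM scaling. Of the angiogenesis genes, Nrp2 at -0.33, Mcam at -0.20 and Flt1 at -0.15 passed when adjusted over the list alone, and 0 passed over all genes.

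Several programmes showed no list call. Immediate early and dissociation genes had a median log2 fold change of 0.14 with 20 of 24 positive (camera adjusted p = 0.0787), and of these Egr3 at 0.45 had the smallest p. Ribosomal protein genes had a median of 0.05 (0.10 with library size only) with 29 of 32 positive (camera adjusted p = 0.0611). Rplp1 of that list at 0.11 and the respiratory chain gene Ndufa2 at 0.13, neither of which passed, changed sign under the GC and length correction, and 72.5% of the sequence of Rplp1 recurs in a single other gene. Mitochondrially encoded genes had a median of -0.09, which was -0.05 with library size only (camera adjusted p = 0.151) and made up 0.206% of counts in control AAV and 0.191% in nANGPTL4 AAV (exact two-sided permutation p = 0.171). Cell cycle genes had a median of 0.04 (camera adjusted p = 0.639), leukocyte adhesion genes one of -0.06 (camera adjusted p = 0.151) and antigen presentation genes one of 0.06 (camera adjusted p = 0.304); with library size only these were 0.08, -0.01 and 0.11.

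The level of Angptl4 raises 2 hypotheses. If it came from other cell types, the other-cell score should take most of it away. With that covariate 64.9% of the log2 fold change was left, 0.41 (SE 0.18) against 0.63 (SE 0.17), which lies between the bounds set for either reading, so other cell types cannot be told apart from a change in the endothelium. If it were part of a PPAR response, since Angptl4 is a known PPAR target, the other 22 measured PPAR targets and fatty acid oxidation genes should be higher as a list. Their median log2 fold change was 0.0316 (0.0752 with library size only) with an interquartile range of 0.17. Of these genes 13 were positive and 9 negative, and the list did not pass (camera adjusted p = 0.510). The median lay below the 0.63 of Angptl4 by more than that range, so as a list they did not rise as far as Angptl4. A smaller PPAR response is not excluded. Reads from the vector, and uptake of RNA from transduced cells, were not tested.

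Clock genes gave a hypothesis of a shifted phase. Cry1 at a log2 fold change of -0.30 and Clock at -0.21 passed when adjusted over the list of 15 alone (0 over all genes, edgeR adjusted p = 0.0718 for both), and the camera adjusted p was 0.692. The mean of the genes that peak with Dbp minus that of those that peak with Arntl was higher in nANGPTL4 AAV by 0.43 on the log2 scale, with overlap between the groups (exact two-sided permutation p = 0.114). A later or earlier harvest may shift Usp2 and Wee1 up and Nfil3 down, but 0 of the 3 moved so at an unadjusted p under 0.05. Their log2 fold changes were 0.11 (SE 0.14), -0.23 (SE 0.13) and -0.22 (SE 0.14), which neither excludes nor bears out a different clock phase at harvest, and harvest times were not given in the sources used here.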
